A study of Homo sapiens with 35 samples.

How the data were processed

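Total RNA from resected ESR1-positive breast tumors was sequenced after depletion of ribosomal RNA, with a stranded total RNA library kit, per the labels' protocols. Participants had been randomized to 20 mg of tamoxifen per day by mouth for 28 days before surgery or to no treatment in that interval, per the labels' protocols. The series held 35 libraries, of which 20 came from the arm without tamoxifen and 15 from the tamoxifen arm, and each library was placed in its arm by its treatment label.

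The authors deposited 1 table of raw counts, whole numbers of reads per gene for 58037 gene identifiers with their symbols, and no normalization was applied to it before deposit as far as its values show. The submitters' processing notes list CASAVA 1.8.2, TopHat2 2.0.13, Picard 1.97 and HTSeq 0.6.1 with the genome build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical copies may be divided in ways that cannot be checked here. Every column was matched to a sample by its title, no row lacked a gene name, and 13943 genes had a total of 0. Gene positions and gene types were taken from the GENCODE annotation of GRCh38, in which 57433 of the identifiers were found without their version number.

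Total counts per library ran from 12226600 to 41709100 in the arm without tamoxifen (median 15416300) and from 9467260 to 20252400 in the tamoxifen arm (median 14364700). A permutation test of the difference in mean total count gave p = 0.0685 (two-sided, 100000 permutations). In simulated counts made from the real means, library sizes and spread, the same test recovered 58.6% of genes changed by 1 on the log2 scale and 96.9% of genes changed by 2, with 3 false calls among 154, for 35 independent libraries. For 27 independent profiles it recovered 43.4% and 88.8% of them, with 1 false call among 131. The simulated genes varied independently of each other and no libraries were near-identical. These counts of false calls therefore do not describe data in which genes vary together or libraries form near-identical sets.

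Genes were filtered with filterByExpr at its default minimums (a count of 10 and a total of 15), which left 18330 genes, and libraries were scaled with TMM factors. The arms were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 ratios of tamoxifen to no tamoxifen, and the standard error of each was derived from its F statistic. CPM values are counts scaled by library size and TMM factor, and log2 CPM values carry a prior count of 2.

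Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over 25 lists, and again with a correlation estimated per list and with fry. The mean log2 CPM of each list per library was compared between arms by permuting arm labels 100000 times. The 25 lists covered estrogen receptor targets, proliferation, p53 targets, cholesterol synthesis, interferon response, antigen presentation, T and NK cells, B and plasma cells, macrophages, mast cells, fibroblasts and matrix, endothelium, adipocytes, myoepithelial and basal cells, luminal epithelium, blood, immediate early genes, heat shock, unfolded protein response, oxidative phosphorylation, hypoxia and glycolysis, apoptosis regulators, growth factor receptors and ligands, replication-dependent histones and mitochondrial transcripts. Relations between the p53 target list and the estrogen receptor target list, the proliferation list and ESR1 were computed within each arm as Pearson and Spearman correlations with permutation p-values, adjusted over the 6 relations.

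The groups, tests, lists, alternative settings and the rule for naming genes were chosen before the data were examined. The rule named ESR1, PGR, CDKN1A, MDM2 and MKI67 in every case, with 1 further gene that is not reported here. It added the 10 genes with the smallest p that rose and the 10 that fell among those past the threshold, with a mean log2 CPM of at least 0 and a symbol other than a bare identifier, a pseudogene, XIST or a Y-linked gene. It also added up to 4 measured members per list with the smallest p. The alternative settings changed the scaling (DESeq2 1.42.0 size factors, upper quartile), the test (DESeq2, limma voom with quality weights, robust edgeR), the filter, the covariates (position in the series' record, surrogate variables from sva 3.50.0, tissue composition scores) and the libraries, each of which was left out in turn.

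Before any test, all pairs of libraries were compared by the correlation of their log2 CPM values. Libraries linked by a correlation of at least 0.97 were treated as a near-identical set. The test kept the 35 libraries apart as designed, and whether the libraries of a set come from separate tumors is not given in the sources used here. As an alternative chosen after seeing the data, the counts of each set were summed, which left 27 profiles, 17 without tamoxifen and 10 with tamoxifen. Values over the 27 profiles are given for the counts of calls and for the main genes and gene lists.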

Results

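RNA abundance was measured in 35 libraries of surgically removed ESR1-positive breast tumors, 15 from participants who took tamoxifen for 28 days before surgery and 20 from participants who did not. Tamoxifen binds the estrogen receptor and blocks its activity in breast epithelium. The study asked how tamoxifen changes gene expression in such tumors and in particular how it bears on p53 target genes, which include genes of cell cycle arrest and apoptosis. Libraries held between 9467260 and 41709100 counts, and the most abundant RNA, RN7SL2 of the signal recognition particle, took 6.64% of all counts. Genes named RN7SL or RN7SK took 3.03% to 28.2% per library without and 3.10% to 21.9% with tamoxifen. Genes of the ribosomal DNA region took 35.9% in tamoxifen replicate 5 (median 0.0419% in its arm), and at most 10.5% without tamoxifen (median 0.166%). The 3 libraries far out on the first principal component were no tamoxifen replicates 7, 8 and 13. The number of genes with a count did not differ between arms beyond its spread, at 28910 ± 1782 (SD, n = 20) without tamoxifen and 29103 ± 1496 (SD, n = 15) with tamoxifen (permutation p = 0.739, two-sided).

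Some libraries of the same arm closely resembled each other. The 11 pairs with a correlation of at least 0.97 lay within arms and formed 6 sets, which held 6 libraries of the arm without tamoxifen and 8 of the tamoxifen arm. The largest set held 4 tamoxifen libraries. The biological coefficient of variation, the spread between libraries beyond counting noise, lay between 0.0245 and 0.223 within these pairs and had a median of 0.5003 over the other 284 pairs of the same arm. These other pairs reached a correlation of 0.9647 and a coefficient of variation of 0.245, so no wide gap set off the near-identical pairs as a whole. The closest pairs did stand apart, at a coefficient of variation of 0.0245 in the set of 4 and 0.0994 in a set of 2 tamoxifen libraries. The highest correlation between libraries of different arms was 0.948. P-values over 35 libraries treat the members of a set as separate tumors, and those over the 27 summed profiles do not.

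**Figure D1:**
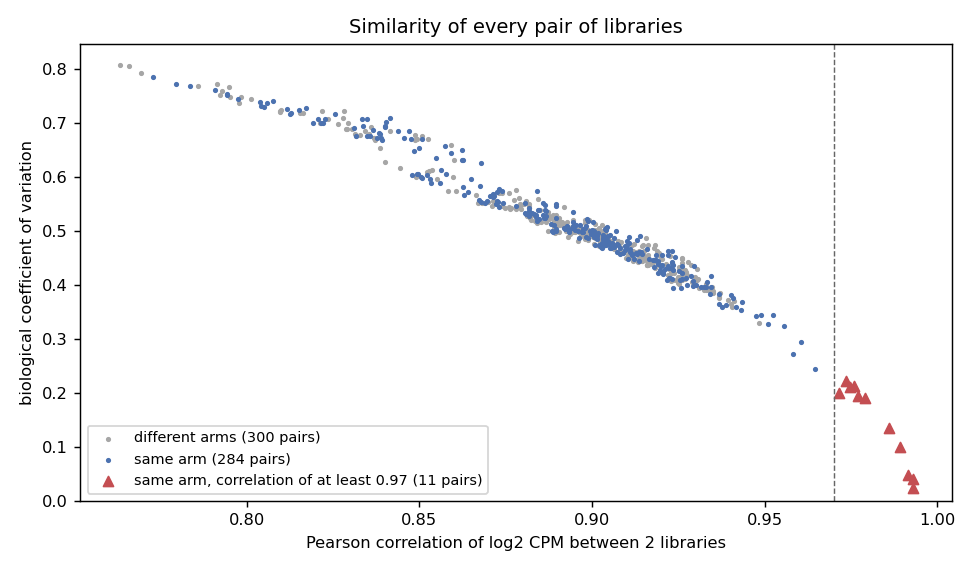
Each point is a pair of libraries, placed by the Pearson correlation of log2 CPM (horizontal axis) and the biological coefficient of variation (vertical axis), with pairs of different arms in grey, pairs of the same arm in blue and near-identical pairs as red triangles. The 11 near-identical pairs lie to the right of the dashed line at 0.97, at a coefficient of variation of at most 0.223.

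The first comparison asked which genes differed between the arms. With tamoxifen, 126 genes rose and 111 fell among 18330 tested. The gene with the smallest p was GDF6, a ligand of the bone morphogenetic protein family (ENSG00000156466.9, chromosome 8, 96142330 to 96160792), at 0.423 ± 0.274 CPM without tamoxifen (SD, n = 20) and 3.98 ± 3.94 CPM with tamoxifen (SD, n = 15). Its log2 fold change was 3.22 (SE 0.47, edgeR adjusted p = 0.000533), and it lay above the median of the other arm in 14 of 15 tamoxifen libraries. It was the 1 gene that also passed over the 27 profiles (log2 fold change 2.86, edgeR adjusted p = 0.0318). GDF6 did not pass with the runs of records as a covariate (2.07, edgeR adjusted p = 0.148), in the first run alone (1.33, 0.825) or the second (3.34, 0.0771), with sets linked at a correlation of 0.95 summed (3.08, 0.124) or with limma and the sets as a random effect (2.59, 0.450).

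ENAH, an actin regulator of the Ena/VASP family on the long arm of chromosome 1 (225486835 to 225653142), rose by 0.80 on the log2 scale (SE 0.14, edgeR adjusted p = 0.00477), from 214 ± 55.7 CPM (SD, n = 20) to 374 ± 116 CPM (SD, n = 15), and lay above the median of the other arm in 15 of 15 tamoxifen libraries. NRP1, a co-receptor for semaphorins and vascular endothelial growth factor on chromosome 10, had a log2 fold change of 0.82 (SE 0.15, edgeR adjusted p = 0.00673) and lay above that median in 15 of 15. NTNG1, a membrane-anchored netrin on chromosome 1, reached 2.95 (SE 0.47, edgeR adjusted p = 0.00141), and NAV3, a neuron navigator that binds microtubules, reached 2.75 (SE 0.46, edgeR adjusted p = 0.00282). The splicing regulator RBM20 had a log2 fold change of 3.86, with a tamoxifen mean of 22.7 ± 31.0 CPM (SD, n = 15). Its medians were 1.13 CPM without and 2.46 CPM with tamoxifen, so a minority of libraries carried much of its rise. LRRC36 (3.43) and TPPP3 (3.10), a gene of the tubulin polymerization promoting family, lie next to each other on chromosome 16, at 67326798 to 67385203 and 67389809 to 67393535. NAV3, LRRC36 and TPPP3 had tamoxifen means of 173, 5.82 and 95.3 CPM but medians of 54.1, 0.984 and 16.7 CPM. Their medians without tamoxifen were 21.4, 0.428 and 8.71 CPM. The ion channel genes TMEM63A (0.90, long arm of chromosome 1) and ANO2 (1.79, chromosome 12) completed the 10. Over the 27 profiles these 9 genes had log2 fold changes from 0.59 (TMEM63A) to 3.04 (RBM20) and unadjusted p from 1.17e-05 (NTNG1) to 0.000960 (TMEM63A), and the smallest edgeR adjusted p was 0.0666, of NTNG1. None of the 9 passed in the first or the second run of records alone, and in the first RBM20 had 0.46, LRRC36 0.96, TPPP3 1.27, NAV3 1.41 and TMEM63A 0.46. With the runs as a covariate NTNG1 and ANO2 passed, and the other 7 did not, RBM20 (1.61), LRRC36 (2.06), TPPP3 (1.91), NAV3 (2.15), ENAH (0.79), NRP1 (0.60) and TMEM63A (0.70).

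The calls were not spread evenly over the genome. The long arm of chromosome 1 held 49 of the 126 genes that rose, or 38.9%, against 4.75% of the tested genes with a position (odds ratio 13.5, Fisher's exact test p = 3.19e-32, a test across genes, which are not independent). The short arm of that chromosome held 5 of them (Fisher's exact test p = 0.562), and the long arm held 2 of the 111 genes that fell. Relative to the genes of the other chromosomes, the mean log2 CPM of the 867 long arm genes was 0.03 ± 0.20 without tamoxifen (SD, n = 20) and 0.33 ± 0.18 with tamoxifen (SD, n = 15; permutation p = 0.000130, two-sided). Over the 27 profiles it was 0.06 ± 0.20 (SD, n = 17) and 0.29 ± 0.17 (SD, n = 10; permutation p = 0.00597). Adjusted over 41 chromosome arms, the permutation p was 0.00451 over the libraries and 0.127 over the profiles. This region was singled out after its values were seen.

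**Figure D2:**
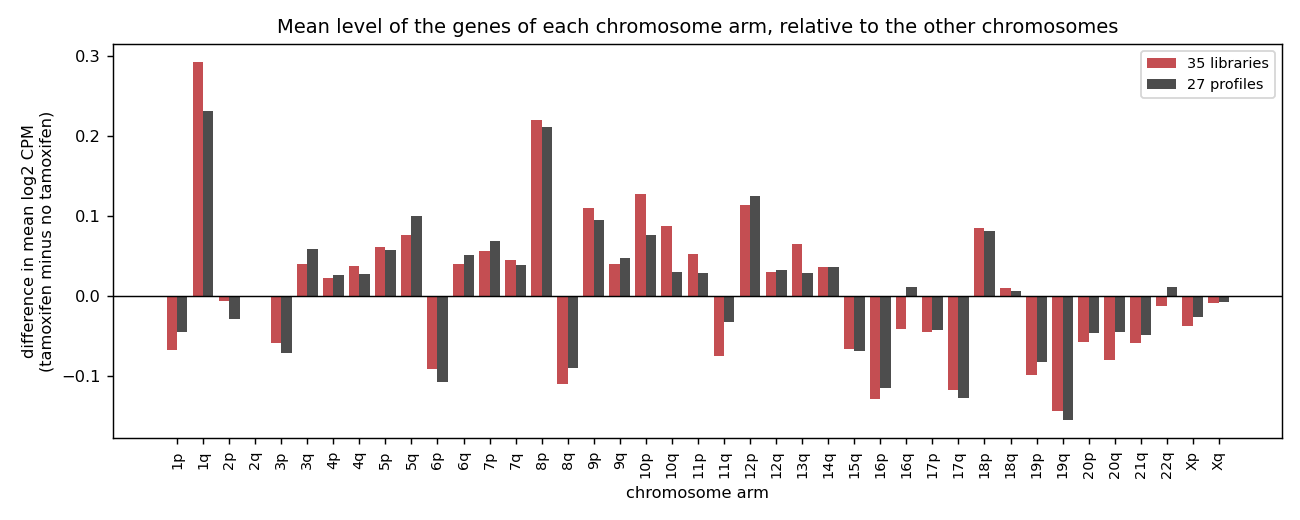
Bars give, for each chromosome arm (horizontal axis), the difference in the mean log2 CPM of its genes between tamoxifen and no tamoxifen, relative to the genes of the other chromosomes (vertical axis), over 35 libraries (red) and 27 profiles (grey). The long arm of chromosome 1 has the highest bars, at 0.29 and 0.23.

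Among the 10 genes with the smallest p that fell, PCSK1, IGSF1 and RIMS2 had the largest log2 fold changes. PCSK1, a convertase that cuts prohormones, had a log2 fold change of -7.94 (SE 1.57, edgeR adjusted p = 0.0102), with a mean of 429 ± 1657 CPM without tamoxifen (SD, n = 20) and 1.74 ± 0.776 CPM with tamoxifen (SD, n = 15). Its median was 1.71 CPM in both arms, so that its fold change came from a minority of libraries, and it moved to -5.11 without no tamoxifen replicate 8. RIMS2, a scaffold of the presynaptic release site, had a log2 fold change of -4.84 (SE 1.01, edgeR adjusted p = 0.0181). Its mean without tamoxifen was 17.1 ± 34.4 CPM (SD, n = 20), but its medians were 0.915 CPM without and 0.394 CPM with tamoxifen. IGSF1, a membrane glycoprotein of the pituitary, had -6.86 (SE 1.43, edgeR adjusted p = 0.0181), and without no tamoxifen replicate 6 its value was -2.95 and no longer passed (edgeR adjusted p = 0.0514). Among the alternative settings other than leaving out 1 library, PCSK1 lost its call in 9 of 18 and turned in 1. RIMS2 lost its call in 10 of 17 and IGSF1 in 10 of 18.

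The other 7 genes changed by smaller steps and in most libraries. URB1-AS1, a long noncoding RNA on chromosome 21 (32393130 to 32393960), had a log2 fold change of -1.19 (SE 0.22, edgeR adjusted p = 0.00544) and lay above the median of the other arm in 0 of 15 tamoxifen libraries. SNORA80A, a small nucleolar RNA inside the gene URB1 on the same strand (32377187 to 32377322), had -1.39 and lay above that median in 1 of 15. ENHO, which encodes adropin, had -2.64, FKBP1B, a ryanodine receptor binding protein, -1.56, ASPHD1 -3.45, ZNF750, a transcription factor of epidermal differentiation, -1.11 and PQBP1, a splicing protein, -0.50, and each lay above the median in 0 of 15. Without tamoxifen ASPHD1 had a mean of 6.91 ± 12.4 CPM but a median of 2.10 CPM, and ENHO 2.63 ± 2.78 and 1.25 CPM (SD, n = 20). Their medians with tamoxifen were 0.514 and 0.318 CPM, so a minority of libraries added to their fold changes. The 10 genes had log2 fold changes from -8.06 (PCSK1) to -0.49 (PQBP1) over the 27 profiles, where the smallest edgeR adjusted p was 0.107, of ZNF750. None passed in the first run of records alone, and in the second SNORA80A did (-1.93, edgeR adjusted p = 0.0449) while PCSK1 turned to 0.40, RIMS2 had -0.37, IGSF1 -2.66, ASPHD1 -1.90 and FKBP1B -0.84. With the runs as a covariate SNORA80A (-1.53) and ZNF750 (-1.37) passed and the other 8 did not. Protein-coding genes overlap SNORA80A (URB1), FKBP1B (MFSD2B), ASPHD1 (KCTD13), ZNF750 (TBCD), PQBP1 (TIMM17B), IGSF1 (OR13H1), TMEM63A (EPHX1), ESR1 (SYNE1) and MDM2 (CPM), and 1 without a symbol here overlaps RIMS2, so part of their counts may belong to these neighbours.

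None of the 237 called genes separated the arms without overlap. Over the 27 profiles, 1 gene rose and 0 fell with edgeR, 2184 genes had an unadjusted p below 0.05 (a median of 1251 and at most 2810 in other splits of the profiles, and at least 2184 in 7 of 100 splits with the real one included), and limma with the sets as a random effect called 0 (1705 below 0.05). The title numbers in the series' record run upwards 3 times, and with these runs as a covariate edgeR called 5 genes, with tissue composition scores as covariates 25, in the first run alone 0 (16 without and 6 with tamoxifen; 1149 below 0.05) and in the second alone 29 (4 and 7). Of the 237 genes called over all libraries, 4 were called again in the same direction in the second run. The libraries of the second run hold near-identical sets and amount to 3 and 4 distinct profiles, which applies to every value of that run. The third run held 0 libraries without and 2 with tamoxifen. Runs and arms were thus partly tied, and a run covariate may also take up part of an arm difference. The composition scores ended the calls of LRRC36 (edgeR adjusted p = 0.0677), NRP1 (0.0864), ANO2 (0.0832), URB1-AS1 (0.0697), FKBP1B (0.108), ASPHD1 (0.139), PQBP1 (0.0610), PCSK1 (0.381), RIMS2 (0.279) and IGSF1 (0.223). All 237 genes kept their direction. The genes of these that rose, LRRC36, NRP1 and ANO2, then had 3.15, 0.67 and 1.63, against 3.43, 0.82 and 1.79 before. The scores were the mean levels of the adipocyte, fibroblast and matrix, and T and NK cell lists. The adipocyte score was itself higher with tamoxifen, by 1.22 (permutation p = 0.0245, 0.204 adjusted over the lists). These covariates may therefore also take up part of an arm difference.

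Genes that stand for the study's question did not pass on their own. ESR1 (ENSG00000091831.21, chromosome 6, 151656691 to 152129619) was at 647 ± 547 CPM without tamoxifen (SD, n = 20) and 253 ± 153 CPM with tamoxifen (SD, n = 15). Its log2 fold change of -1.35 (SE 0.39) missed the threshold (edgeR adjusted p = 0.0650). It lay above the median of the other arm, 510 CPM, in 1 of 15 tamoxifen libraries, and over the 27 profiles its log2 fold change was -1.28 (unadjusted p = 0.0101). In the second run of records alone it turned to 0.25. PGR, the progesterone receptor and an estrogen receptor target, had a log2 fold change of -0.45 (SE 0.46, edgeR adjusted p = 0.646). CDKN1A, which encodes the cell cycle inhibitor p21, had 0.36 (SE 0.27, edgeR adjusted p = 0.489), and MDM2, which encodes a ubiquitin ligase, had 0.17 (SE 0.12, edgeR adjusted p = 0.451). MKI67, the gene of the Ki-67 antigen of dividing cells, had equal means of 72.1 ± 58.9 CPM (SD, n = 20) and 72.3 ± 95.8 CPM (SD, n = 15) but medians of 63.4 and 17.8 CPM, with a log2 fold change of 0.0033 (SE 0.51, edgeR adjusted p = 0.998).

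**Figure D3:**
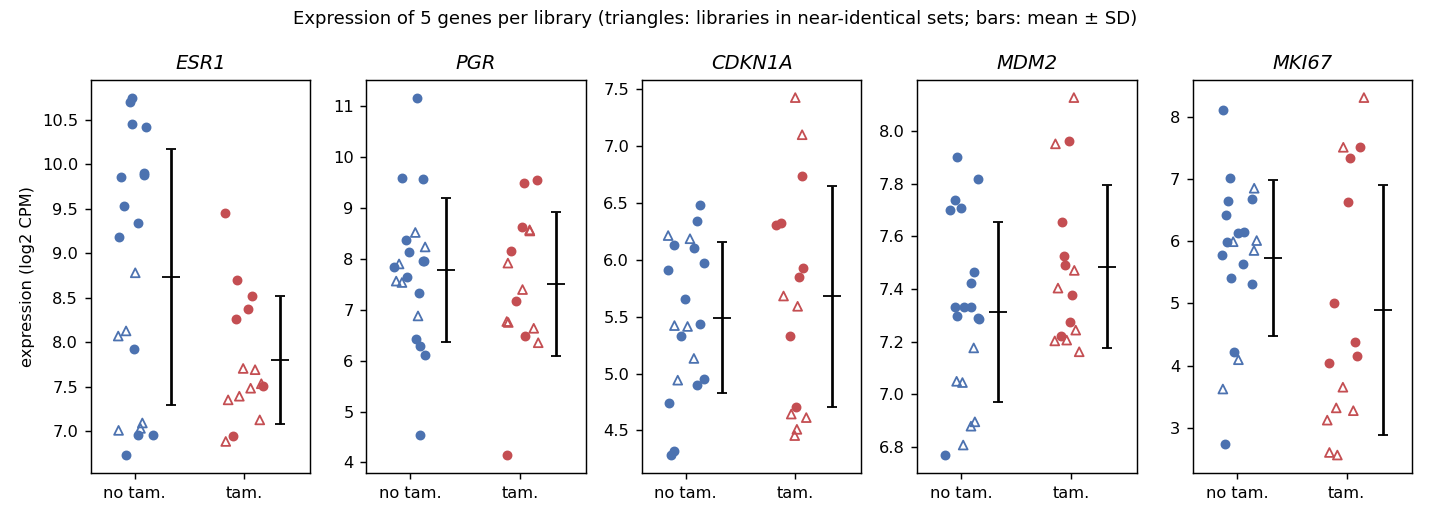
Points are libraries, with log2 CPM on the vertical axis and the arm on the horizontal axis, for ESR1, PGR, CDKN1A, MDM2 and MKI67; open triangles are libraries of near-identical sets, and bars are the mean ± SD of all libraries of the arm. For ESR1, 1 of 15 tamoxifen libraries lies above the median of the arm without tamoxifen.

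The second comparison asked whether genes induced by estradiol through ESR1 were lower with tamoxifen. By camera at its preset correlation they ranked lower as a group (adjusted p = 0.00941). Of the 44 measured genes, 37 had a negative log2 fold change, and the median was -0.42. This call was lost with an estimated correlation (camera adjusted p = 0.637) and by fry (adjusted p = 0.288). It was also lost with tissue composition scores (0.213) or the runs of records (0.329) as covariates. IL17RB, a receptor for interleukin 17 family ligands, fell by 1.72 on the log2 scale (SE 0.43, edgeR adjusted p = 0.0403), and 0 members rose and 43 did not pass over all genes. IL17RB had -1.74 over the 27 profiles (edgeR adjusted p = 0.330). Adjusted over the list alone, 3 genes fell and 1 rose, and 0 did over the profiles. GREB1, a cofactor of the estrogen receptor, had -1.37 (SE 0.41), XBP1, a transcription factor of the secretory pathway, had -0.76 (SE 0.24), and the small heat shock protein gene HSPB8 had 2.05 (SE 0.64). Each had an edgeR adjusted p of 0.0347 over the list alone, and HSPB8 lay above the median of the other arm in 7 of 15 tamoxifen libraries. The mean log2 CPM of the list per library was 6.07 ± 0.62 (SD, n = 20) and 5.86 ± 0.34 (SD, n = 15), a difference within the spread (permutation p = 0.260). The camera adjusted p was 0.0322 in the first run of records alone and 0.566, with the list on the higher side, in the second.

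Cell cycle genes of S phase, G2 and mitosis were compared next, since they are a common readout of short endocrine treatment. The list ranked lower with tamoxifen by camera (adjusted p = 2.05e-07), with 36 of 48 members at a negative log2 fold change and a median of -0.18. With an estimated correlation the call was lost (adjusted p = 0.676). Of its members, 0 rose and 0 fell over all genes and also adjusted over the list alone. The smallest p belonged to the replication helicase genes MCM7 (-0.48, SE 0.17, edgeR adjusted p = 0.130) and MCM2 (-0.54, SE 0.23, edgeR adjusted p = 0.197), the thymidine kinase TK1 (-1.15, SE 0.49, edgeR adjusted p = 0.198) and the transcription factor E2F1 (-0.90, SE 0.42, edgeR adjusted p = 0.240). The list's mean of 3.54 ± 0.96 (SD, n = 20) and 2.88 ± 1.40 (SD, n = 15) did not differ beyond its spread (permutation p = 0.105), and over the 27 profiles the difference was -0.51 (permutation p = 0.271). The camera adjusted p was 0.997 in the first run of records alone, with the list on the higher side, and 0.0444 in the second. With the runs as a covariate it was 0.0547 and the call was lost.

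The p53 target list addressed the question named in the study's design, whether these genes differed after tamoxifen. Its 53 measured members had a median log2 fold change of 0.08, with 37 positive and 16 negative, and the list did not pass (camera adjusted p = 0.175; 0.676 with an estimated correlation). No member rose or fell over all genes or adjusted over the list alone (edgeR, 0 of 53). The smallest p belonged to ZMAT3, which encodes an RNA-binding protein (0.40, SE 0.15, edgeR adjusted p = 0.157), the membrane rupture gene NINJ1 (-0.36, SE 0.14, edgeR adjusted p = 0.169), the kinase gene PLK2 (0.60, SE 0.24, edgeR adjusted p = 0.172) and the mitochondrial reductase gene FDXR (-0.38, SE 0.19, edgeR adjusted p = 0.286). The mean log2 CPM of the list was 4.71 ± 0.17 (SD, n = 20) and 4.80 ± 0.14 (SD, n = 15, permutation p = 0.107). Over the 27 profiles the difference was 0.14 (95% bootstrap interval 0.02 to 0.26, permutation p = 0.0534, 0.355 adjusted over the 25 lists). The camera adjusted p was 0.00891 in the first run of records alone, 0.981 in the second and 0.0711 over the 27 profiles (0.573 with an estimated correlation). With sets linked at a correlation of 0.98 or 0.95 summed, the list passed on the higher side (camera adjusted p = 0.0486 and 0.0262).

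Among the other 22 lists, 5 ranked higher and 3 lower with tamoxifen by camera, and 0 of these 8 held with an estimated correlation. Markers of tissue outside the tumor epithelium made up the higher lists. All 17 endothelial genes had positive log2 fold changes, with a median of 0.56 (camera adjusted p = 2.75e-10; adjusted p = 0.510 with an estimated correlation). The endothelial list did not pass in the second run of records alone (camera adjusted p = 0.0788). None of its genes passed over all genes, and 13 rose when adjusted over the list alone, among them SOX18 (0.89, SE 0.25), EMCN (0.89, SE 0.26), VWF, the von Willebrand factor (0.88, SE 0.26), and the angiopoietin receptor TEK (0.60, SE 0.18). The mean log2 CPM of the endothelial list was 4.42 ± 0.45 (SD, n = 20) and 4.94 ± 0.59 (SD, n = 15, permutation p = 0.00461, 0.115 adjusted over the lists). Over the profiles the difference was 0.59 (95% bootstrap interval 0.22 to 1.01, permutation p = 0.00545, 0.136 adjusted over the lists).

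All 19 adipocyte genes were also on the higher side, with a median of 1.22 (camera adjusted p = 4.13e-10; adjusted p = 0.510 with an estimated correlation), and 12 rose when adjusted over the list alone, with 0 over all genes and 0 adjusted over the list alone over the 27 profiles. LEP, the gene of leptin, had a log2 fold change of 2.34 (SE 0.69), the adipokine CFD 1.16 (SE 0.36), the retinol carrier RBP4 1.63 (SE 0.57) and lipoprotein lipase LPL 1.35 (SE 0.48). In the first run of records alone the adipocyte list did not pass (camera adjusted p = 0.130). Fibroblast and matrix genes had a median of 0.31 (18 of 22 positive, camera adjusted p = 0.000154; adjusted p = 0.676 with an estimated correlation), with MMP2 at 0.72 (SE 0.38) and PDGFRB at 0.40 (SE 0.27). The fibroblast list turned to the lower side in the second run of records (0.0861) and lost its call with voom (0.378), with surrogate variables (0.611) and without the 3 libraries far out on the first principal component (0.126). Macrophage genes had a median of 0.07 (13 of 21 positive, camera adjusted p = 0.00838; adjusted p = 0.791 with an estimated correlation; 0.671 on the lower side in the second run), with the mannose receptor MRC1 at 1.06 (SE 0.38) and the scavenger receptor MARCO at 1.33 (SE 0.58). In the blood list (6 of 8 positive, median 0.40, camera adjusted p = 0.00941; adjusted p = 0.510 with an estimated correlation; 0.963 on the lower side in the second run), the neutrophil calprotectin gene S100A8 rose by 1.805 on the log2 scale (SE 0.44, edgeR adjusted p = 0.0352), and its partner S100A9 had 1.36 (SE 0.38, edgeR adjusted p = 0.0566). Both lie on the long arm of chromosome 1, and over the 27 profiles they had 1.57 and 1.15 (edgeR adjusted p = 0.330 and 0.383).

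Replication-dependent histone genes, whose transcripts lack a poly(A) tail, ranked lower, with 61 of 63 measured genes negative and a median of -0.39 (camera adjusted p = 9.96e-12; adjusted p = 0.510 with an estimated correlation). HIST1H2AE (-0.999, SE 0.22, edgeR adjusted p = 0.0256) and HIST1H1E (-0.64, SE 0.15, edgeR adjusted p = 0.0276) fell, and 10 genes fell when adjusted over the list alone. These 2 genes had -0.80 and -0.51 over the 27 profiles (edgeR adjusted p = 0.347 and 0.340). Histone genes took 0.187% ± 0.0601 of all counts (SD, n = 20) and 0.144% ± 0.0600 (SD, n = 15; permutation p = 0.0473, unadjusted). The list's mean had an adjusted permutation p of 0.235, and over the 27 profiles a permutation p of 0.193. Nuclear genes of oxidative phosphorylation had a median of -0.25 (28 of 33 negative, camera adjusted p = 0.000165, 0.637 with an estimated correlation). The call was also lost with voom (camera adjusted p = 0.232), surrogate variables (0.231), composition scores (0.319) and without the libraries far out on the first principal component (0.0920). Adjusted over the list alone, 4 genes fell and 1 rose. CYC1 had -0.96 (SE 0.27), COX5B -0.34 (SE 0.10) and ATP5F1 -0.38 (SE 0.11), and the gene that rose, SDHC (0.41, SE 0.13), also lies on the long arm of chromosome 1. Genes of the unfolded protein response had a median of -0.22 (18 of 22 negative, camera adjusted p = 0.00224, 0.510 with an estimated correlation). Adjusted over the list alone 5 fell, with the chaperone genes HYOU1 at -0.49 (SE 0.15) and HSPA5 at -0.53 (SE 0.18). The list's call was also lost with the runs as a covariate (camera adjusted p = 0.0547) and in the first (0.244) and second run alone (0.156). It was lost too with surrogate variables (0.123) and composition scores (0.213).

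The 14 remaining lists did not pass, although single members did. EREG, the gene of the EGFR ligand epiregulin, rose by 3.79 on the log2 scale (SE 0.98, edgeR adjusted p = 0.0422) within the growth factor list (camera adjusted p = 0.171). BIK, a proapoptotic BCL2 family gene, rose by 1.72 (SE 0.44, edgeR adjusted p = 0.0416) within the apoptosis list (0.579). HK2, hexokinase 2, fell by 0.80 (SE 0.20, edgeR adjusted p = 0.0389) within the hypoxia and glycolysis list (0.0541). EREG had 2.61, BIK 0.86 and HK2 -0.82 over the 27 profiles (edgeR adjusted p = 0.395, 0.442 and 0.338). With tamoxifen EREG had a mean of 32.3 ± 48.1 CPM but a median of 1.43, and BIK 26.6 ± 32.7 and 9.40 (SD, n = 15). Their medians without tamoxifen were 0.305 and 6.77 CPM. With the runs of records as a covariate, 3 lists did pass, T and NK cells (0.00257) and B and plasma cells (0.0102) on the higher side and hypoxia and glycolysis (0.0168) on the lower. The camera adjusted p without it was 0.0637 for T and NK cells, 0.0806 for B and plasma cells, 0.470 for mast cells, 0.938 for myoepithelial and basal cells and 0.232 for luminal epithelium. It was 0.681 for cholesterol synthesis, 0.636 for interferon response, 0.579 for antigen presentation, 0.344 for immediate early genes, 0.101 for heat shock and 0.7502 for mitochondrial transcripts. The interferon, antigen presentation and myoepithelial lists had negative medians (-0.10, -0.03 and -0.68) while their means per library were higher with tamoxifen by 0.14, 0.14 and 0.40. The mast cell list had a median of 0.09 and a mean log2 fold change of -0.12, and camera placed it on the higher side. Over the 27 profiles, camera at its preset correlation passed 17 of the 25 lists and 0 with an estimated correlation. The differences in mean over the profiles were 1.11 for fibroblasts and matrix (unadjusted permutation p = 0.0567), 0.45 for macrophages (0.147) and 1.10 for adipocytes (0.102). They were 0.70 for blood (0.0198), -0.21 for oxidative phosphorylation (0.0757) and -0.15 for the unfolded protein response (0.181), also unadjusted. After adjustment over the 25 lists the permutation p for blood was 0.248, and 0 lists passed over the libraries or over the profiles. Adjusted over a list alone, edgeR over the profiles called 12 endothelial genes, 1 gene of the blood list and 0 genes of the other 23 lists.

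**Figure D4:**
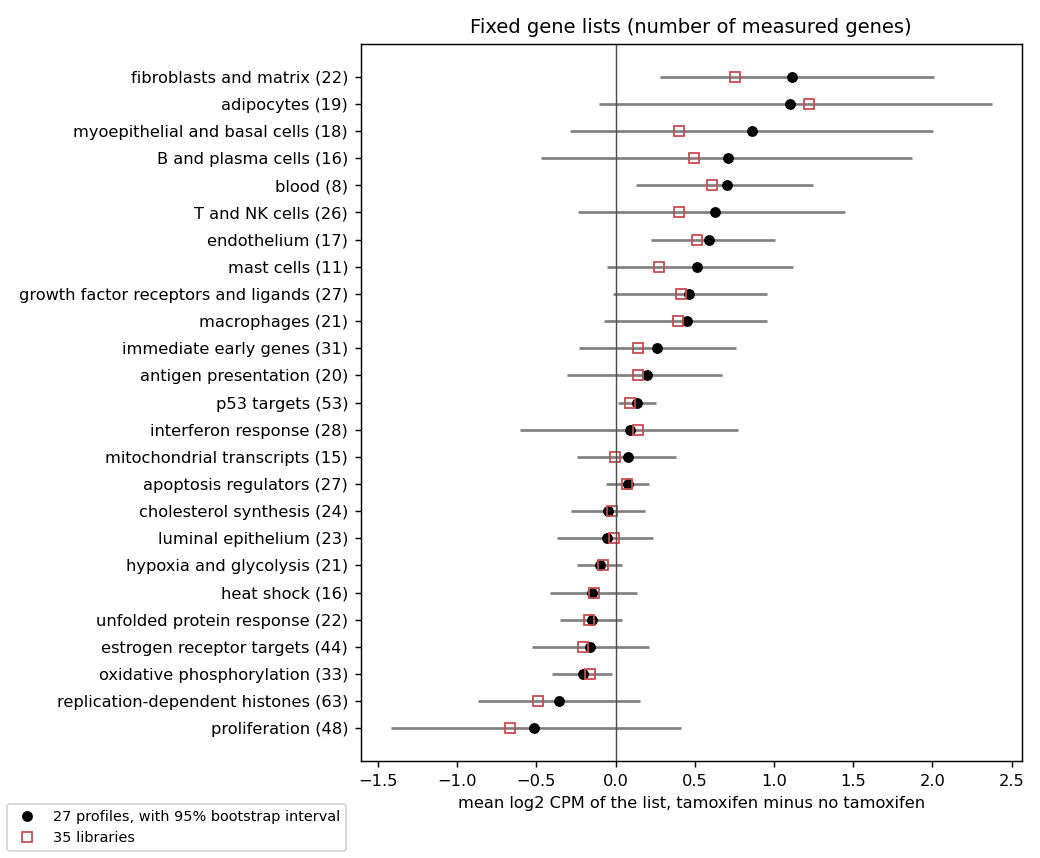
Points give the difference in the mean log2 CPM of each list between tamoxifen and no tamoxifen (horizontal axis) for the 25 lists (vertical axis, with the number of measured genes), over 27 profiles (black, with 95% bootstrap intervals) and over 35 libraries (red squares). The endothelial difference over the profiles is 0.59, with an interval of 0.22 to 1.01, and that of the p53 target list is 0.14.

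The last comparison asked whether the level of p53 targets followed that of ESR1, its targets or proliferation across tumors of the same arm. In the tamoxifen arm the p53 target list was higher where estrogen receptor targets were higher (Pearson r = 0.624, Spearman rho = 0.607, permutation p = 0.0124 and 0.0186, n = 15) and where proliferation genes were higher (r = 0.553, rho = 0.707, permutation p = 0.0336 and 0.00437). Adjusted over the 6 relations, the Pearson values missed the threshold (0.0746 and 0.101), the rank correlation with proliferation passed (0.0262) and that with estrogen receptor targets did not (0.0557). With genes scaled to z-scores, rho with proliferation was 0.789 (adjusted permutation p = 0.00474). Without the 2 libraries farthest from the median, r was 0.666 with estrogen receptor targets and 0.385 with proliferation. The rank correlation with proliferation was then 0.643 and did not pass (adjusted permutation p = 0.0616). Over the 10 summed tamoxifen profiles r was 0.554 (adjusted permutation p = 0.236) and 0.435 (0.243), and rho with proliferation was 0.539 (0.171). Within the second run of records r was 0.756 with estrogen receptor targets and 0.907 with proliferation (exact permutation p = 0.0397 and 0.0407, n = 7; 0.0610 for both when adjusted), but rho with proliferation was 0.464 (exact permutation p = 0.302). These 7 libraries include near-identical sets of 2 and 3. Within the first run r was 0.537 and -0.475 (exact permutation p = 0.269 and 0.321, n = 6), and rho with proliferation was -0.657 (exact permutation p = 0.175).

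In the arm without tamoxifen the p53 target list had r = 0.307 with estrogen receptor targets (rho = 0.203, permutation p = 0.188 and 0.389, n = 20) and r = -0.433 with proliferation (rho = -0.217, permutation p = 0.0560 and 0.357), and both rested on the 2 libraries farthest from the median, without which r was -0.0361 and 0.0191. With ESR1 itself, r was -0.290 without tamoxifen (rho = -0.388, permutation p = 0.219 and 0.0910) and 0.416 with tamoxifen (rho = 0.289, permutation p = 0.121 and 0.295). The difference between arms in the relation with proliferation had a permutation p of 0.0327 (0.0982 adjusted over 3 relations) over the libraries and 0.123 over the profiles. For ESR1 these values were 0.0721 (0.108 adjusted) and 0.0563, and for estrogen receptor targets 0.353 and 0.436. The second run held 4 libraries without tamoxifen, and no correlation was computed for them.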

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

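The settings with summed sets, the random effect for sets, the left-out PC1 libraries, the left-out ribosomal DNA library and 2 of the settings for relations were chosen after seeing the data, and the others before. In this section, p-values of lists are adjusted camera p-values unless fry is named, and the cause was not tested for any change unless it is given. The DESeq2 test and the random effect gave no list values, and the composition setting has no values for the 3 lists it is built from. Against 126 genes higher and 111 lower, 237 in all, edgeR with DESeq2 size factors called 236 in all, with upper-quartile factors 247, with the robust fit 234 and with the stricter filter 194. DESeq2 called 446 and 487, voom with quality weights 632 and 425, no filter 212 and 213, and surrogate variables 350 and 240. The position in the series' record as a covariate gave 2 and 3, the first run of records alone 0 and 0 and the second 15 and 14 (with fewer libraries), and tissue composition scores 16 and 9. Summed sets gave 1 and 0 (linked at a correlation of 0.97), 8 and 2 (at 0.98) and 0 and 0 (at 0.95), and voom with the sets as a random effect gave 0 and 0. Without the PC1 libraries the counts were 132 and 73, and without the ribosomal DNA library 96 and 75. Of the 237 main calls, 228 were called again in the same direction with DESeq2, 193 with voom and quality weights and 183 without a filter. Surrogate variables kept 172 of them, composition scores 22 and the second run 4. Without the PC1 libraries 129 were kept, and without the ribosomal DNA library 157. Leaving out each library in turn gave 44 to 191 higher and 29 to 191 lower. The ends were tamoxifen replicate 13 (44 and 29), tamoxifen replicate 2 (191 and 171) and no tamoxifen replicate 20 (171 and 191). Other libraries that moved a count by over 1.5 times were no tamoxifen replicate 1 (72 higher) and tamoxifen replicates 7 (56 lower), 8 (68 lower), 9 (61 lower), 11 (53 and 36), 12 (60 and 42), 14 (70 and 65) and 15 (65 and 48). Tamoxifen replicates 11, 12, 13 and 14 form the near-identical set of 4, and replicates 7 and 8 a set of 2.

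The estrogen receptor target list stayed lower but did not pass with the record position as a covariate (0.329), with composition scores (0.213), with an estimated correlation (0.637) and by fry (0.288), and it turned to the higher side in the second run (0.566). The proliferation list stayed lower without passing with the record position (0.0547), an estimated correlation (0.676) and fry (0.385), and it turned in the first run (0.997). The p53 target list passed on the higher side in the first run (0.00891) and with sets summed at 0.98 (0.0486) and at 0.95 (0.0262). Leaving out 1 library changed no call of these 3 lists. The number of other lists that passed, 8, moved to 4 in the second run, 5 with surrogate variables, 5 with composition scores, 15 with sets summed at 0.97, 15 at 0.95, 0 with an estimated correlation and 0 by fry. Among the values of the other lists outside the leave-one-out fits, 281 kept their direction and call, 32 gained a call, 35 lost it and 45 turned. Apart from an estimated correlation and fry, which ended all 8 calls, calls were lost with the record position (blood 0.135, unfolded protein response 0.0547), in the first run (adipocytes 0.130, unfolded protein response 0.244, histones 0.0799) and in the second (endothelium 0.0788, unfolded protein response 0.156). They were also lost with voom (fibroblasts 0.378, blood 0.164, oxidative phosphorylation 0.232), with surrogate variables (fibroblasts 0.611, unfolded protein response 0.123, oxidative phosphorylation 0.231), with composition scores (blood 0.144, unfolded protein response 0.213, oxidative phosphorylation 0.319), without the PC1 libraries (fibroblasts 0.126, oxidative phosphorylation 0.0920) and with sets summed at 0.95 (macrophages 0.109). The gained calls came with the record position (T and NK cells 0.00257, B and plasma cells 0.0102, hypoxia 0.0168), in the first run (T and NK cells 6.94e-07, B and plasma cells 3.98e-05, interferon 0.000105, antigen presentation 0.000209, mast cells 0.00891, hypoxia 0.00108, apoptosis 0.0318), without a filter (heat shock and hypoxia, both 0.0119), with voom (heat shock 0.0117) and without the ribosomal DNA library (heat shock 0.00657). With sets summed at 0.97, 0.98 and 0.95, T and NK cells (0.00244, 0.00771, 0.0186), B and plasma cells (0.0147, 0.00741, 0.0339) and hypoxia (0.0172, 0.0199, 0.00669) passed. At 0.97 and 0.95, mast cells and heat shock (both 0.0445 and 0.0396) and immediate early genes (0.0445 and 0.0167) did, at 0.97 luminal epithelium (0.0346), and at 0.95 myoepithelial cells (0.000795, higher) and growth factors (0.0186).

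In the second run alone these lists turned: interferon response (0.450), antigen presentation (0.408), T and NK cells (0.554), B and plasma cells (0.785), macrophages (0.671), mast cells (0.137), fibroblasts and matrix (0.0861), myoepithelial cells (0.0414), luminal epithelium (0.143), blood (0.963), apoptosis regulators (0.986), growth factors (0.724) and mitochondrial transcripts (0.570). In the first run alone, cholesterol synthesis (0.178), myoepithelial cells (0.521), immediate early genes (0.108) and mitochondrial transcripts (0.137) turned. With the record position as a covariate, cholesterol synthesis (0.414), myoepithelial cells (0.0547), luminal epithelium (0.776), immediate early genes (0.782), growth factors (0.914) and mitochondrial transcripts (0.0957) turned. With composition scores, cholesterol synthesis (0.319), mast cells (0.521), myoepithelial cells (0.00659), luminal epithelium (0.583), immediate early genes (0.0419) and growth factors (0.782) turned. With surrogate variables, cholesterol synthesis (0.252), myoepithelial cells (0.268) and immediate early genes (0.962) turned, and without the PC1 libraries cholesterol synthesis (0.343), myoepithelial cells (0.0501) and immediate early genes (0.849). With voom, myoepithelial cells (0.495) and immediate early genes (0.560) turned, with no filter myoepithelial cells and apoptosis regulators (both 0.859), and with upper-quartile factors myoepithelial cells (0.892). With sets summed at 0.97 and 0.95, interferon response (0.988 and 0.369) and mitochondrial transcripts (0.771 and 0.703) turned, and without the ribosomal DNA library interferon response did (0.730). In the leave-one-out fits, lists that turned ranged from 0.204 to 0.953 (cholesterol synthesis), 0.0605 to 0.988 (interferon response), 0.0605 to 0.934 (antigen presentation), 0.424 to 0.996 (myoepithelial cells) and 0.162 to 0.962 (mitochondrial transcripts). Leaving out 1 library also gained 43 calls of other lists, for hypoxia and glycolysis in 16 of 35 fits (0.0191 to 0.111), T and NK cells in 12 (9.5e-05 to 0.589), B and plasma cells in 12 (0.00182 to 0.566), heat shock in 2 (0.00657 to 0.237) and immediate early genes in 1 (0.0149 to 0.948).

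Of the values of named genes outside those fits, 309 kept direction and call, 139 lost the call, 1 gained it and 13 turned. In the second run ESR1 had a log2 fold change of 0.25, PGR 0.96 and PCSK1 0.40. PGR had 0.071 with the record position and 0.031 with surrogate variables, and CDKN1A had -0.18 with voom. MKI67, whose log2 fold change was close to 0, turned to -0.0069 with DESeq2 size factors, -0.0090 with DESeq2, -1.20 with voom, -0.030 without a filter, -0.51 with surrogate variables, -0.56 with the random effect and -0.39 without the ribosomal DNA library. Leaving out each library moved PGR from -0.64 to 0.037 and MKI67 from -0.39 to 0.24. ESR1 passed with DESeq2 (-1.34, adjusted p = 0.0164), without tamoxifen replicate 1 (-1.53, edgeR adjusted p = 0.0464) and without no tamoxifen replicate 20 (-1.39, edgeR adjusted p = 0.0456).

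In the arm without tamoxifen, the correlation of the p53 target list with estrogen receptor targets turned to -0.0361 without the 2 farthest libraries and to -0.136 over summed profiles without the 2 farthest, and that with proliferation turned to 0.0191 and 0.0701. With tamoxifen, that with proliferation turned to -0.475 in the first run. In simulated libraries at the real depth 58.6% of genes changed by 1 on the log2 scale were recovered, and depth was not varied.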

Other observations

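The tests of shared extreme genes, of a whole-arm shift on chromosome 1 and of neuroendocrine genes, and the comparison of all chromosome arms, were chosen only after the results were seen. Beside the long arm of chromosome 1, 2 arms had lower mean levels with tamoxifen over the 35 libraries, 17q (-0.12, adjusted permutation p = 0.0141 over 41 arms) and 19q (-0.14, adjusted permutation p = 0.0470). Of the 785 genes of 17q, 12 fell and 3 rose, and of the 679 genes of 19q, 5 fell and 1 rose. Over the 27 profiles the differences were -0.13 and -0.16, and no arm passed (adjusted permutation p = 0.127 for 17q and 1q, 0.188 for 19q).

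A list of 25 neuroendocrine genes was put together after members such as PCSK1 and RIMS2 were seen to fall. Of the 15 that were measured, 12 had negative log2 fold changes and 10 fell, but 0 did over the 27 profiles, and the camera p of 0.00511 became 0.291 with an estimated correlation. The list holds the genes that prompted it, so these counts and p-values are no independent support. Those that fell included the synaptic vesicle gene SYP (-3.38, SE 0.86, edgeR adjusted p = 0.0416), SNAP25 of the vesicle fusion complex (-4.43, SE 1.02, edgeR adjusted p = 0.0276), the secretogranin gene SCG2 (-4.93, SE 1.26, edgeR adjusted p = 0.0416) and SEZ6 (-6.01, SE 1.32, edgeR adjusted p = 0.0241). SYT1, RAB3C and STMN2 had positive values (0.87, 0.38 and 0.48) and did not pass.

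For the 237 genes called over 35 libraries, 2 of 100 splits into groups of the same sizes called as many, with 947 the highest of the other splits. That excludes chance only if every library is a separate unit. What produced the 947 calls of that split was not tested. With the near-identical sets kept whole, 14 of 100 splits called as many, so chance cannot be excluded for them. It cannot be excluded either for the 1 gene called over the 27 profiles, since 34 of 100 splits called at least 1 and the highest called 32.

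The 11 near-identical pairs were the first pattern. Splits that kept each set within an arm called at least 237 genes in 14 of 100, with 1009 the highest of the others, so near-identical libraries counted as separate tumors may account for the number of calls. The loss of calls on summing was larger than that after leaving out as many libraries outside the sets, which left a 5th percentile of 92.9 and a median of 275.5 calls. Those fits kept every near-identical set whole, so they cannot tell what fewer separate tumors alone would give. The near-identical pairs shared at least 72.7% of their extreme genes with tamoxifen (other pairs at most 34.6%) and at least 28.6% without, where 2 of 3 pairs exceeded the other pairs (at most 56.25%). Since the pairs were chosen by the correlation of the same values, repeats and similar but separate tumors cannot be told apart by this share.

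The calls on the long arm of chromosome 1 were the second pattern. The 816 genes of the arm that were not called had a median log2 fold change 0.32 above that of uncalled genes of other chromosomes, which fits a shift of the whole arm. The difference in the mean level of the arm was 0.23 over the profiles and 0.29 over the libraries. Counting near-identical libraries as separate tumors need not shrink a mean difference, so these values cannot decide whether it produced the calls. Over the profiles no arm passed (permutation p adjusted over 41 arms was 0.127 for this one). The 1 gene called there, GDF6, lies on chromosome 8. An imbalance between arms in tumors with a copy gain of this arm is a hypothesis that was not tested, as DNA copy number was not analysed here.

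The neuroendocrine genes were the third pattern. The median over the list of the difference between arm medians was -0.29, against a median fitted log2 fold change of -3.50, so a few tumors of the arm without tamoxifen may carry the difference. The list's mean level stood more than 3 median absolute deviations above the median in 4 libraries, all without tamoxifen. The difference in the list's mean was -0.76 over the libraries (permutation p = 0.136) and -0.84 over the profiles (permutation p = 0.220). An effect of tamoxifen on such tumors stays open and was not tested.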
